A study of Homo sapiens with 27 samples.

How the data were processed

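RNA libraries were made with a TruSeq mRNA kit from the neuroblastoma line SK-N-SH and the pancreatic lines QGP-1 and BON-1, each carrying an empty vector, full-length MAML3 or MAML3 lacking exon 1, in 3 biological replicates per group and 27 libraries in all. Per the submitters' processing notes, adapters were removed with Trimmomatic, reads were aligned to hg19 with HISAT2 and abundances were estimated with StringTie, with no versions given. The values are estimated counts per gene, deposited by the authors as whole numbers with 1 column per library. The step from StringTie abundances to counts, the gene annotation and the strand of counting are not stated. Low values heap at 5 units (7317 values), but 1 to 4 units are common too (4436, 3539, 3600 and 4312). What 1 sequenced fragment is worth is therefore not known. Of 23234 genes listed, 4 symbols appeared on a second line with identical values, and 23230 symbols were used.

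The design was written for FPKM values and limma. Since the table holds counts, its stated fallback of edgeR on counts was used. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and matplotlib 3.10.9. Each line was fitted on its own with its 9 libraries: genes were filtered with filterByExpr, libraries scaled with TMM, and the 3 comparisons tested with edgeR's quasi-likelihood F test, with p adjusted by Benjamini-Hochberg and a threshold of 0.05. All adjusted p for genes come from this test unless another tool is named. Levels are CPM after this scaling. Fold changes are fitted log2 values, given with an SE. Log2 CPM has a prior count of 2. Differences in effect between lines came from 1 model of all 27 libraries. For a gene at 0 in every library of a group, the fold change is a lower bound against a floor of 15 units per library, which is 3 fragments if each is worth 5 units, an assumption. Genes near 0 in a group are given as CPM with no fold change. The floor covers counting error only.

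Gene lists were written before the data were examined, as were the comparisons, the naming rule and most alternatives. Of 28 lists, 27 had at least 3 measured members and were tested in each comparison with camera from limma at a preset correlation of 0.01. Each list was also tested with an estimated correlation and with fry. List p were adjusted over the 27 lists of a comparison. The number of members passing the gene test is given with the number passing when adjusted over the list alone. A further 6 lists, chosen after the data had been seen, appear in the closing section only.

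The genes named follow a rule: MAML3 in every library; in each comparison with vector the 10 largest and 10 smallest fold changes among genes past the threshold, with all 3 libraries of a group on 1 side of all 3 others and a mean of at least 2 CPM in the higher group. For dEx1 against FL and for the contrasts between lines, 5 of each were taken, without the condition on separate groups for the contrasts. The rule also takes up to 4 members of each list past the threshold, or up to 2 as values where none passed, and up to 5 genes called the same way with both constructs in a line. Uncharacterised loci and small RNAs were left out, and the text may give only the first genes of a ranking. Contrast genes at or near 0 in a group are given as CPM only.

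Overlap between the constructs within a line was set against 100 simulations of unchanged groups sharing the vector libraries. Replicates were taken as paired where the residual correlation of libraries with the same number was at least 0.1 in every pair, which held for BON-1 and for dEx1 against FL in QGP-1. Alternatives were no filter on low counts, a minimum mean of 2 CPM, DESeq2 size factors, DESeq2 in place of edgeR, a replicate block, all 27 libraries in 1 fit, only the 6 libraries compared, and leaving out each library in turn. Added after seeing the data were counts divided by 5, a robust estimate of spread, MAML3 left out of the scaling, and terms for libraries that stood apart. Each comparison was also repeated on the 10 splits of its 6 libraries, and the contrasts between lines on 40 draws.

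The method was tested on simulated data made from the table, with 200 genes changed. In SK-N-SH at FL against vector, 14% of genes changed 1.5-fold, 56% of those changed 2-fold and 96% of those changed 4-fold were called. In BON-1 these were 0%, 34% and 92%, and in QGP-1 6%, 36% and 88%. False calls were 7 of 138, 6 of 118 and 7 of 120.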

Results

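RNA was sequenced from 3 human neuroendocrine cell lines transfected to overexpress MAML3, a member of the Mastermind-like family of transcriptional coactivators known from Notch signalling. SK-N-SH is a neuroblastoma line, and BON-1 and QGP-1 are pancreatic neuroendocrine tumour lines. Each line received an empty vector, full-length MAML3 (FL) or MAML3 lacking exon 1 (dEx1), with a V5 tag at the carboxyl end of the protein, and was harvested on day 3. Each of the 9 groups had 3 biological replicates, which made 27 libraries. The total estimated count per library ran from 85367579 to 97874108 in SK-N-SH vector, 81739994 to 105566404 in SK-N-SH FL and 84575626 to 91842622 in SK-N-SH dEx1. In BON-1 the totals were 73026244 to 87892041 for vector, 92353136 to 110350759 for FL and 97111371 to 105303262 for dEx1. In QGP-1 they were 79395945 to 92435640 for vector, 92977932 to 120254457 for FL and 84030641 to 97298951 for dEx1. These totals are in the deposited units, whose worth in fragments is not stated. Levels below are CPM, counts scaled by library size, as mean ± SD over a group's 3 libraries. Changes are log2 fold changes with SE.

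MAML3 (hg19 chromosome 4, 140637907 to 141075338, 5 exons, exon 1 at 141074014 to 141075338) was far above vector in each library that received a construct, which matches the labels. In SK-N-SH its level was 21.2 ± 6.95 CPM with vector, 11590 ± 3817 CPM with FL and 9084 ± 4330 CPM with dEx1 (SD, n = 3), a rise of 9.09 (SE 0.56, adjusted p = 0.000525) and 8.74 (SE 0.55, adjusted p = 0.00130) on the log2 scale. In BON-1 it rose from 65.1 ± 4.15 CPM to 3879 ± 1234 CPM with FL and 3518 ± 428 CPM with dEx1, by 5.90 (SE 0.27, adjusted p = 5.34e-05) and 5.76 (SE 0.26, adjusted p = 6.24e-05). In QGP-1 it rose from 73.4 ± 29.9 CPM to 5885 ± 3304 CPM with FL and 4622 ± 1672 CPM with dEx1, by 6.33 (SE 0.63, adjusted p = 0.0193) and 5.98 (SE 0.62, adjusted p = 0.0355). Between dEx1 and FL, MAML3 did not pass the test in any line, with differences of -0.35 in SK-N-SH (SE 0.39, adjusted p = 0.577), -0.14 in BON-1 (adjusted p = 1.00) and -0.35 in QGP-1 (SE 0.50, adjusted p = 1). A count per gene cannot tell the construct from native MAML3, or FL from dEx1. The QGP-1 values kept their size when any 1 library was left out, at 5.88 to 6.68 for FL and 5.69 to 6.27 for dEx1, while the call was lost without any vector library or dEx1 replicates 2 or 3 for FL (adjusted p up to 0.133) and without any library except FL replicate 1 for dEx1 (up to 0.225).

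**Figure D1:**
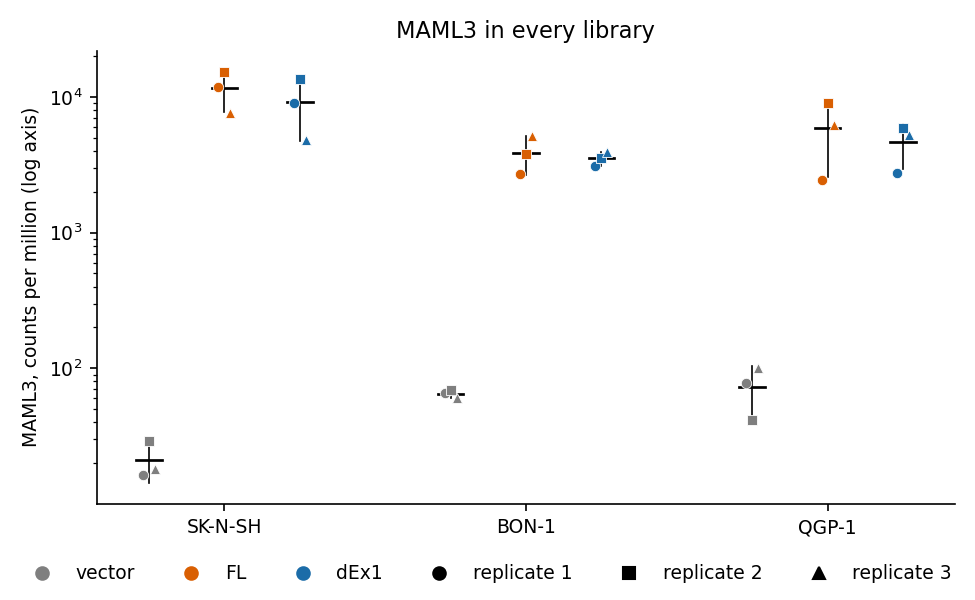
MAML3 level in each of the 27 libraries, in CPM on a log axis, by line and construct; the point's shape gives the replicate, the black bar is the group mean and the thin bar the SD. Vector libraries sit between 16.3 and 100.5 CPM and construct libraries between 2421 and 15250 CPM.

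Within lines, some libraries stood apart from the others of their group on principal components of log2 CPM. In SK-N-SH the first component (40.7% of the variance) parted dEx1 from FL, with vector replicate 3 at 40.01, on the side of the dEx1 libraries, and vector replicates 1 and 2 at -28.3 and -28.5. The second component (19.2%) held replicate 3 of each SK-N-SH group apart from replicates 1 and 2. In BON-1 vector replicate 1 stood alone on the first component, at -107, and on the second (25.3%) replicate 3 of FL and dEx1 stood apart from replicates 1 and 2. Vector replicates 1 to 3 were at 24.7, -33.4 and 50.8 there. The QGP-1 libraries formed 2 clusters on the first component (39.7%) that did not follow the constructs. Cluster 1 held replicate 1 of all 3 groups and replicate 2 of FL and dEx1, and cluster 2 held vector replicate 2 and replicate 3 of all 3 groups.

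**Figure D2:**
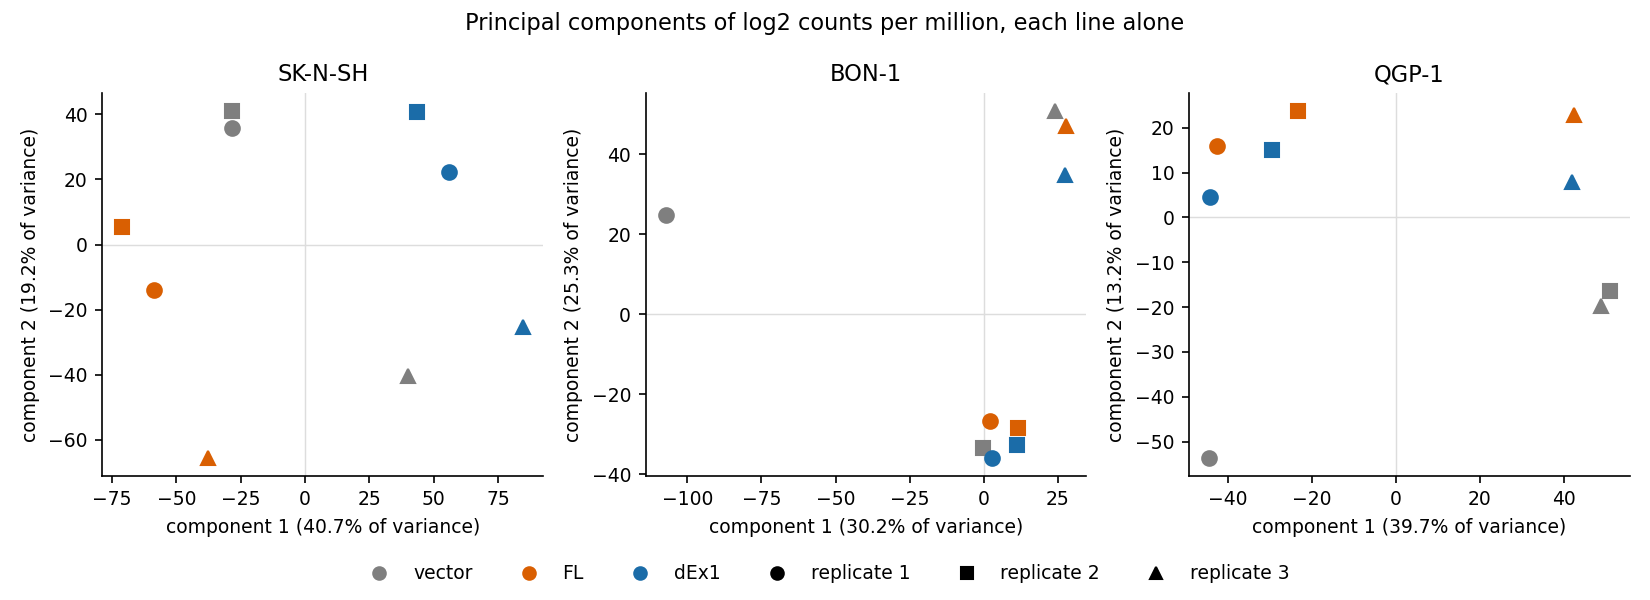
Scores of the 9 libraries of each line on the first and second principal component of log2 CPM (axes in score units, with the percent of variance), 1 panel per line; colour gives the construct and shape the replicate. SK-N-SH replicate 3 and BON-1 vector replicate 1 lie apart from their groups, and QGP-1 splits into 2 clusters that mix constructs.

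The comparison of FL with vector in SK-N-SH addresses which transcripts change when neuroblastoma cells express full-length MAML3. Of 14 measured inflammatory genes driven by NF-kB, 8 passed the test upward and none downward. CCL20, a chemokine that attracts lymphocytes and dendritic cells, rose by 5.78 on the log2 scale (SE 0.70, adjusted p = 0.0108), from 2.52 to 139 ± 81.6 CPM (SD, n = 3). IL1B, the cytokine interleukin 1 beta, rose by 6.08 (SE 0.89, adjusted p = 0.0229), from 2.35 ± 1.36 to 159 ± 120 CPM. CXCL1, a neutrophil chemokine, rose by 5.76 (SE 0.79, adjusted p = 0.0166), and CCL2, a chemokine for monocytes, rose by 1.44 (SE 0.18, adjusted p = 0.0133), from 234 ± 59.7 to 634 ± 76.3 CPM. The call of CCL20 was lost without vector replicate 2, that of CCL2 without vector replicate 1 or FL replicate 2, that of CXCL1 without vector replicates 1 or 2 or FL replicates 1 or 2, and that of IL1B without those 4 or dEx1 replicate 1. The highest adjusted p over the alternatives of CCL20, CCL2, CXCL1 and IL1B were 0.0530, 0.0945, 0.0899 and 0.0899. For this NF-kB list the median fold change was 1.47, with 10 members higher adjusted over the list alone. The set test gave an adjusted p of 3.87e-18 with the preset correlation and adjusted p = 0.177 with an estimated correlation. With a term for replicate 3 against replicates 1 and 2, the libraries that stood apart, 10 members passed and the set test gave adjusted p = 0.0276 with an estimated correlation.

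In the same SK-N-SH comparison the metalloprotease genes MMP10, MMP3 and MMP1 rose and MMP24 fell. Stromelysin genes MMP10 and MMP3 rose by 3.37 (SE 0.28, adjusted p = 0.00314) and 3.15 (SE 0.30, adjusted p = 0.00434), MMP10 from 7.71 ± 2.55 to 79.9 ± 19.3 CPM and MMP3 from 26.8 ± 2.17 to 237.7 ± 75.1 CPM (SD, n = 3). MMP1, the interstitial collagenase, rose by 2.91 (SE 0.34, adjusted p = 0.0103), from 74.1 ± 31.9 to 555 ± 108 CPM, and TIMP1, an inhibitor of these enzymes, by 1.08 (SE 0.17, adjusted p = 0.0257). These were the 4 of 24 measured proteases and inhibitors that passed the test. In the list the median was 0.07 and the mean 0.52, with 10 members higher and 2 lower adjusted over the list alone. Camera, the set test, gave an adjusted p of 2.43e-05 and adjusted p = 0.177 with an estimated correlation. The calls of MMP10 and MMP3 held under every alternative run, that of MMP1 was lost without FL replicate 2 (adjusted p up to 0.0543 over its alternatives), and that of TIMP1 without any of the 3 vector libraries, FL replicates 1 or 2 or dEx1 replicate 1 (up to 0.116). MMP24, which is outside the list, fell by 1.72 (SE 0.28, adjusted p = 0.0261), from 20.4 to 6.19 CPM. Its call was lost without vector replicates 1 or 2, FL replicate 1 or dEx1 replicate 1 (up to 0.120).

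Of the genes of hypoxia and glycolysis, ADM, which encodes the vasodilator adrenomedullin, rose in SK-N-SH with FL by 1.37 (SE 0.25, adjusted p = 0.0354), from 41.6 to 107.5 CPM. It was the only 1 of 16 measured members to pass, and all 16 fold changes were positive (median 0.33, 6 higher adjusted over the list alone, set test adjusted p = 5.28e-06, adjusted p = 0.177 with an estimated correlation). Of 13 measured targets of p53, 3 passed downward. BTG2, an antiproliferative gene, fell by 1.32 (SE 0.19, adjusted p = 0.0221), from 70.9 to 28.4 CPM, FDXR fell by 0.81 (SE 0.12, adjusted p = 0.0246), and TP53INP1 fell by 1.08 (SE 0.17, adjusted p = 0.0259). All 13 were negative (median -0.55, 6 lower adjusted over the list alone, set test adjusted p = 1.35e-07, adjusted p = 0.177 with an estimated correlation). Leaving out vector replicates 1 or 2, FL replicates 1 or 2 or dEx1 replicate 1 ended the calls of BTG2, FDXR and TP53INP1 (adjusted p up to 0.107, 0.116 and 0.270 over their alternatives). The call of ADM was lost without any library except FL replicate 3 (up to 0.128).

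Among Notch genes in SK-N-SH with FL, HEY1, a direct target of Notch, fell by 1.49 (SE 0.30, adjusted p = 0.0483), from 7.39 ± 1.26 to 2.63 ± 1.04 CPM (SD, n = 3). The call of HEY1 was lost without any library except FL replicate 3 (adjusted p up to 0.141 over its alternatives). HEY1 was the only 1 of 11 measured Notch targets to pass. For these targets the median was -0.37, with 2 higher and 4 lower adjusted over the list alone. The set test gave an adjusted p of 0.122 (adjusted p = 0.423 with an estimated correlation). Of 14 Notch ligands, receptors and coactivators, KAT2B, a histone acetyltransferase, fell by 0.49 (adjusted p = 0.0460), a call lost without any 1 of the 9 libraries (up to 0.156), and the list had a median of -0.03, a mean of 0.30 and a set test adjusted p of 0.921, with a downward direction. The 21 interferon response genes had a median of 0.03 and a mean of -0.08, with a downward set test at an adjusted p of 0.921. WNT7B, a Wnt ligand, rose by 3.89 (SE 0.37, adjusted p = 0.00434), from 0.721 to 10.8 CPM, and passed under every alternative run. VCAN, the matrix proteoglycan versican, fell by 0.70 (SE 0.11, adjusted p = 0.0249), from 929 to 571 CPM, a call lost without vector replicates 1 or 2, FL replicates 1 or 2 or dEx1 replicate 1 and in a fit of all 27 libraries (up to 0.796). The 23 lists not called in this comparison had adjusted p of 0.0630 or more.

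Over all 14674 genes tested in SK-N-SH, 255 passed at FL against vector, 137 higher and 118 lower, of which 136 differed at least 2-fold; 2302 genes had an unadjusted p under 0.05. The largest rises were in genes near 0 in vector. EREG, which encodes the growth factor epiregulin, was at 28.9 ± 22.9 CPM against 0.00999 ± 0.0173 CPM (SD, n = 3; adjusted p = 0.0150), WNT1 at 2.52 ± 0.553 CPM (adjusted p = 0.0150), the antisense gene MORC2-AS1 at 2.29 ± 1.11 CPM (adjusted p = 0.0284) and IL36G at 2.09 ± 0.943 CPM (adjusted p = 0.0279). The last 3 were at 0 in all vector libraries, which makes them at least 15.6-fold, 14.2-fold and 13.0-fold higher against a minimum of 15 units per library. CSF3, the granulocyte growth factor, rose by 7.49 (SE 1.08, adjusted p = 0.0221), to 36.4 ± 33.3 CPM. The strand of counting is not stated, so reads of MORC2-AS1 and MORC2 may not be told apart. The largest falls among named genes were ASPN, a small matrix proteoglycan, at -3.15 (SE 0.41, adjusted p = 0.0137), GCSAM at -3.04 (SE 0.61, adjusted p = 0.0481), HSD17B14 at -2.79 (SE 0.33, adjusted p = 0.0103), CPA4 at -2.09 (SE 0.39, adjusted p = 0.0409) and ANGPT2, a regulator of vessel growth, at -2.08 (SE 0.42, adjusted p = 0.0497). The count of 255 fell to 51 and 54 without vector replicates 1 and 2, to 32 and 21 without FL replicates 1 and 2, and to 48, 150 and 140 without dEx1 replicates 1, 2 and 3. It was 1117 with the term for replicate 3 and 1168 with DESeq2. The call of HSD17B14 was lost without FL replicate 2 and those of WNT1 and ASPN without FL replicates 1 or 2 (adjusted p up to 0.0669, 0.101 and 0.162 over their alternatives). That of EREG was lost without vector replicates 1 or 2 or FL replicates 1 or 2, and those of MORC2-AS1, IL36G and CSF3 without these or dEx1 replicate 1 (up to 0.0849, 0.128, 0.128 and 0.0849). Those of GCSAM, CPA4 and ANGPT2 were lost without any FL or dEx1 library, and also without vector replicates 2 or 3 for GCSAM, replicate 1 for CPA4 and replicates 1 or 2 for ANGPT2 (up to 0.180, 0.201 and 0.190). Of the 47 genes named for this comparison, MMP10, MMP3 and WNT7B passed under every alternative. Of the 47, 42 lost their call with only the 6 libraries compared and 21 in a fit of all 27.

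The comparison of dEx1 with vector in SK-N-SH addresses the same question for MAML3 without exon 1. The interferon response fell: 16 of 21 measured members passed downward, and all 21 were negative, with a median of -1.63. IFIT2, an antiviral gene, fell by 3.80 on the log2 scale (SE 0.50, adjusted p = 0.00883), from 1887 ± 548 to 136 ± 76.4 CPM (SD, n = 3). OAS2, which senses double-stranded RNA, fell by 2.76 (SE 0.43, adjusted p = 0.0141), from 460.4 ± 31.0 to 68.1 ± 39.0 CPM, OASL, a relative of it, fell by 2.12 (SE 0.33, adjusted p = 0.0141), and the transcription factor IRF1 fell by 1.75 (SE 0.27, adjusted p = 0.0140), from 187 to 55.7 CPM. All 21 were lower adjusted over the list alone. Camera, the set test, gave an adjusted p of 7.13e-33 and adjusted p = 0.143 with an estimated correlation. With the term for replicate 3, 21 of 21 passed and the median was -1.67. The IFIT2 call was lost without dEx1 replicate 1 (adjusted p = 0.0517, the highest over its alternatives, with 9.45e-16 the lowest), and those of OAS2, OASL and IRF1 without vector replicate 1 or dEx1 replicate 1 (up to 0.0593, 0.0575 and 0.0579).

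The 10 largest falls with dEx1 in SK-N-SH included interferons themselves and chemokines. IFNB1, interferon beta, fell by 5.79 (SE 0.99, adjusted p = 0.0174), from 14.9 ± 7.51 to 0.263 ± 0.357 CPM (SD, n = 3), and IFNL1, a type III interferon, fell by 5.65 (SE 1.10, adjusted p = 0.0271), to 0.190 CPM from 9.78 CPM. The chemokines CCL5 and CXCL11 fell by 5.02 (SE 0.69, adjusted p = 0.0101) and 5.46 (SE 0.74, adjusted p = 0.00957), CCL5 from 511 ± 308 to 15.8 ± 9.19 CPM. TNFSF10, the death ligand TRAIL, fell by 5.36 (SE 0.41, adjusted p = 0.00205), from 18.3 ± 4.97 to 0.441 ± 0.165 CPM. CACNA1I was at 0.0415 CPM against 5.39 ± 1.76 CPM with vector (adjusted p = 0.0117), CD74 at 0.0461 against 3.27 ± 2.02 CPM (adjusted p = 0.00870), ZBP1 at 0.0415 against 2.12 CPM (adjusted p = 0.0362), MMP13 at 0.0626 against 2.19 CPM (adjusted p = 0.0234) and CR1L at 0.135 against 3.87 CPM (adjusted p = 0.0299). CD74 and TNFSF10 passed under every alternative. CACNA1I, CCL5 and CXCL11 were lost without dEx1 replicate 1 (adjusted p up to 0.0521, 0.0569 and 0.0525 over their alternatives), IFNB1 and IFNL1 also without vector replicates 1 or 2 or dEx1 replicate 3 (up to 0.0691 and 0.102), and MMP13 without vector replicates 1 or 2 or any dEx1 library (up to 0.0804). ZBP1 and CR1L were lost without vector replicates 1 or 2, FL replicates 1 or 2 or dEx1 replicate 1, and ZBP1 also without dEx1 replicate 3 (up to 0.120 and 0.117).

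Of the 14 NF-kB genes 5 also passed downward with dEx1 in SK-N-SH, among them NFKBIA, which encodes an inhibitor of NF-kB, at -0.81 (SE 0.13, adjusted p = 0.0151), NFKB2 at -0.75 (SE 0.11, adjusted p = 0.0130) and TNFAIP3 at -2.98 (SE 0.56, adjusted p = 0.0229). The median was -1.57, with 10 lower adjusted over the list alone. Camera put the list at 6.68e-11 (adjusted p = 0.256 with an estimated correlation). ATF3, a stress-induced transcription factor, fell by 2.45 (SE 0.32, adjusted p = 0.00884), from 95.2 to 17.4 CPM, as the only 1 of 14 ATF4 and ER stress targets to pass (median -0.43, 8 lower adjusted over the list alone, set test 5.76e-05, adjusted p = 0.389 with an estimated correlation). Of 18 immediate early and MAPK targets 5 passed downward, with JUNB at -1.24 (SE 0.16, adjusted p = 0.00883) and the phosphatase DUSP5 at -0.90 (SE 0.11, adjusted p = 0.00721). The median was -0.33, with 5 lower and 1 higher adjusted over the list alone. Tested as a set, these genes gave 0.00156 (adjusted p = 0.143 with an estimated correlation). Of 24 proteases and inhibitors 4 passed downward, with PLAUR, the urokinase receptor, at -1.20 (SE 0.19, adjusted p = 0.0140), CTSL at -0.68 (SE 0.10, adjusted p = 0.0141) and MMP1 at -1.76 (SE 0.33, adjusted p = 0.0236), from 74.1 to 21.9 CPM. The median was -0.25, with 7 lower adjusted over the list alone. The set test for them gave 0.00429 (adjusted p = 0.291 with an estimated correlation). Of 14 mesenchymal neuroblastoma markers 3 passed downward, IRF2, RUNX2 and FOSL1, at -1.46 (SE 0.26, adjusted p = 0.0185), -0.74 (SE 0.15, adjusted p = 0.0350) and -0.85 (SE 0.18, adjusted p = 0.0388). The median was -0.36, with 4 lower adjusted over the list alone. Camera put the list at 0.00396 (adjusted p = 0.143 with an estimated correlation). ATF3 and DUSP5 passed under every alternative, and the JUNB call was lost without dEx1 replicate 1 (adjusted p = 0.0506). NFKBIA, NFKB2, PLAUR and CTSL were lost without vector replicates 1 or 2 or dEx1 replicate 1, TNFAIP3 also without dEx1 replicate 3, and MMP1 without vector replicates 1 or 2 or any dEx1 library (adjusted p up to 0.0680, 0.0646, 0.202, 0.0821, 0.0925 and 0.0950 over their alternatives). IRF2 was lost without vector replicates 1 or 2 or dEx1 replicates 1 or 2, and RUNX2 and FOSL1 also without dEx1 replicate 3 and FL replicate 1, with RUNX2 lost without FL replicate 2 as well (up to 0.0794, 0.514 and 0.242).

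Among Notch genes HES4, a Notch-responsive repressor, fell in SK-N-SH with dEx1 by 2.52 (SE 0.25, adjusted p = 0.00375), from 27.8 ± 8.77 to 4.86 ± 0.388 CPM (SD, n = 3), and passed under every alternative. It was the only 1 of 11 Notch targets to pass. The median was -0.27, with 2 lower adjusted over the list alone. Tested as a set, these genes gave 0.109 (adjusted p = 0.381 with an estimated correlation). RBPJ, the DNA-binding partner of Notch, fell by 0.64 (SE 0.10, adjusted p = 0.0145), from 72.7 to 46.7 CPM, and the ligand gene DLL1 fell by 1.92 (SE 0.36, adjusted p = 0.0237). The RBPJ and DLL1 calls were lost without vector replicates 1 or 2 or dEx1 replicates 1 or 3 (adjusted p up to 0.0661 and 0.0959 over their alternatives). These were the 2 of 14 Notch ligands, receptors and coactivators that passed (median -0.14, 3 lower adjusted over the list alone, set test 0.114). The 13 cholesterol synthesis genes had a median of 0.23 and 0 calls with edgeR (set test upward 0.0319, adjusted p = 0.414 with an estimated correlation). The 23 ribosomal proteins had a median of 0.16 and 0 calls with edgeR (set test upward 0.00429, adjusted p = 0.698 with an estimated correlation), and 0 of either list passed adjusted over the list alone. The 19 lists not called had adjusted p of 0.0813 or more.

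At dEx1 against vector 656 SK-N-SH genes passed, 122 higher and 534 lower, with 333 differing at least 2-fold and 3328 at an unadjusted p under 0.05. Among the largest rises were NHLH1, a neuronal transcription factor, at 2.48 (SE 0.52, adjusted p = 0.0361), CAMK2A, a calcium-dependent kinase, at 2.17 (SE 0.37, adjusted p = 0.0174), LRRN4CL at 1.82 (SE 0.40, adjusted p = 0.0409) and, further down, FAM117A at 1.36 (SE 0.16, adjusted p = 0.00712), from 5.87 to 15.0 ± 2.14 CPM (SD, n = 3). FAM117A passed under every alternative. The other 3 calls were lost without vector replicates 1 or 2 or dEx1 replicates 1 or 2. Those of NHLH1 and LRRN4CL were also lost without FL replicate 1, that of NHLH1 without FL replicate 2 and that of LRRN4CL without dEx1 replicate 3 (adjusted p up to 0.137 for NHLH1, 0.381 for CAMK2A and 0.317 for LRRN4CL). The share of calls that were lower moved with replicate 3: with the term for it 2714 genes passed, 1271 higher and 1443 lower, and without vector replicate 3, the library on the dEx1 side of the first component, 2558 passed, 1216 higher and 1342 lower. The count was 108 and 154 without vector replicates 1 and 2, 369 and 427 without FL replicates 1 and 2, and 80, 350 and 268 without dEx1 replicates 1, 2 and 3, and 8 of 58 named genes passed under every alternative. Of the 58, 25 lost their call with only the 6 libraries compared and 25 in a fit of all 27.

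Few genes changed the same way with both constructs in SK-N-SH. Across 14673 genes without MAML3, the FL and dEx1 effects had a correlation of 0.00747 (rho -0.0680) over genes, which are not independent replicates, where 100 simulations of unchanged groups sharing their vector libraries gave a median of 0.498 (0.420 to 0.544). The covariance was 0.00564 against a simulated 0.186. In calls, 2 genes were higher with both constructs (1.12 for independent lists), 10 lower with both (4.29 for independent lists) and 34 went in opposite directions. The simulations gave a median of 0. Among those lower with both were the transcription factor KLF5 (-0.53 with FL, -0.53 with dEx1), the RNA-binding protein ZFP36 (-0.85, -1.10) and RP2 (-0.58, -0.62). The FL calls of KLF5 and ZFP36 were lost without vector replicates 1 or 2, FL replicates 1 or 2 or dEx1 replicate 1, and that of RP2 without these or vector replicate 3 (adjusted p up to 0.255, 0.123 and 0.139 over their alternatives). With dEx1 the call of ZFP36 held under every alternative run, that of KLF5 was lost without dEx1 replicate 1 and that of RP2 without vector replicate 1 or dEx1 replicate 1 (up to 0.160 and 0.0680 for the last 2). Among genes of at least 2 CPM the correlation was -0.257.

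The comparison of dEx1 with FL in SK-N-SH addresses what exon 1 changes. The inflammatory groups differed: all 14 NF-kB genes and all 21 interferon response genes were lower with dEx1 and passed. CCL20 was lower by -6.74 (SE 0.74, adjusted p = 0.00112), CCL2 by -2.29 (SE 0.19, adjusted p = 0.000374), NFKBIA by -1.56 (SE 0.13, adjusted p = 0.000436) and OAS1 by -1.94 (SE 0.27, adjusted p = 0.00218). CXCL10, an interferon-induced chemokine, was at 2.77 ± 2.35 CPM with dEx1 against 145 ± 35.5 CPM with FL (SD, n = 3; log2 difference -5.71, SE 0.79, adjusted p = 0.00224). For the NF-kB genes the median was -3.01, with all 14 lower adjusted over the list alone. The set test gave an adjusted p of 2.32e-20 (adjusted p = 0.178 with an estimated correlation, 0.0478 with the term for replicate 3). For the interferon response the median was -1.77, with all 21 lower adjusted over the list alone. The set test for them gave 1.13e-17 (adjusted p = 0.347 with an estimated correlation). Of 24 proteases and inhibitors 12 were lower and 5 higher (6 and 12 adjusted over the list alone for higher and lower; median -0.37, set test 2.24e-05, adjusted p = 0.178 with an estimated correlation). MMP10 was at 3.49 ± 0.557 CPM against 79.9 ± 19.3 CPM (-4.52, SE 0.30, adjusted p = 0.000238), MMP3 at 15.3 against 237.7 CPM (-3.96, SE 0.31, adjusted p = 0.000317) and MMP1 at 21.9 against 555 CPM (-4.66, SE 0.37, adjusted p = 0.000337). These 8 genes passed under every alternative.

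**Figure D3:**
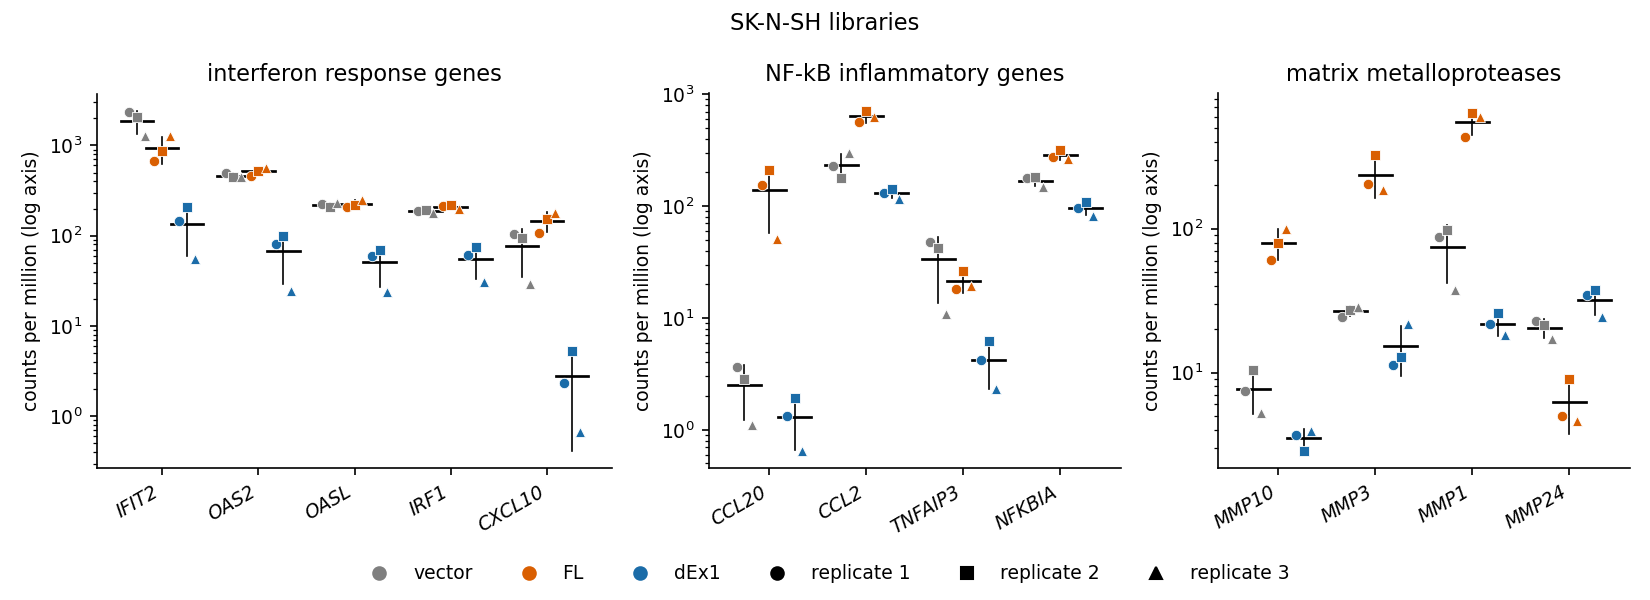
Levels of selected genes in the 9 SK-N-SH libraries, in CPM on a log axis, by construct; the point's shape gives the replicate, the black bar is the group mean and the thin bar the SD. MMP10 means are 7.71 CPM with vector, 79.9 CPM with FL and 3.49 CPM with dEx1, and IFIT2 means are 1887 CPM with vector and 136 CPM with dEx1.

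Other SK-N-SH lists, of which none passed with an estimated correlation, had members passing between dEx1 and FL. Of 13 targets of p53, 5 passed upward with dEx1, with FDXR at 1.02 (SE 0.12, adjusted p = 0.00136), TP53INP1 at 1.24 (SE 0.17, adjusted p = 0.00219) and ZMAT3 at 1.29 (SE 0.20, adjusted p = 0.00342). The median was 0.40, with 5 higher and 1 lower adjusted over the list alone. Camera put the list at 0.00595 (adjusted p = 0.403 with an estimated correlation). Of 13 cholesterol synthesis genes 6 passed upward, with the squalene epoxidase gene SQLE at 0.61 (SE 0.09, adjusted p = 0.00266) and MVD at 1.07 (SE 0.21, adjusted p = 0.00901). The median was 0.50, with 7 higher adjusted over the list alone. Tested as a set, these genes gave 0.00294 (adjusted p = 0.347 with an estimated correlation). Of 16 hypoxia and glycolysis genes 7 passed downward, with ADM at -1.93 (SE 0.25, adjusted p = 0.00179) and hexokinase HK2 at -0.81 (SE 0.09, adjusted p = 0.00113). The median was -0.33, with 8 lower adjusted over the list alone. The set test for them gave 0.000892 (adjusted p = 0.347 with an estimated correlation). Of 14 ATF4 and ER stress targets 7 passed downward, with ATF4 itself at -0.67 (SE 0.12, adjusted p = 0.00582). The median was -0.68, with 11 lower adjusted over the list alone. Camera put the list at 0.000393 (adjusted p = 0.417 with an estimated correlation). Of 18 immediate early and MAPK targets 7 passed downward and 1 upward, with DUSP5 at -0.96 (SE 0.11, adjusted p = 0.00112) and JUNB at -1.08 (SE 0.16, adjusted p = 0.00273). The median was -0.46, with 7 lower and 2 higher adjusted over the list alone. Tested as a set, these genes gave 0.0154 (adjusted p = 0.323 with an estimated correlation). Of 11 Notch targets, the receptor gene NOTCH3 and HEY1 were higher at 1.66 (SE 0.26, adjusted p = 0.00362) and 1.35 (SE 0.30, adjusted p = 0.0138), HES4 was lower at -2.24 (SE 0.24, adjusted p = 0.00108) and ID1 at -0.44 (SE 0.13, adjusted p = 0.0394), with a median of -0.06 and a set test adjusted p of 0.864. The ID1 call was lost without any library except vector replicates 2 and 3 (adjusted p up to 0.578 over its alternatives). The matrix genes VCAN and FBN1 were higher at 1.15 (SE 0.11, adjusted p = 0.000753) and 1.14 (SE 0.14, adjusted p = 0.00138), VCAN losing its call in a fit of all 27 libraries (0.230, the highest over its alternatives, with 2.45e-20 the lowest). The 19 lists not called had adjusted p of 0.0760 or more.

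Between dEx1 and FL 3226 of 14674 SK-N-SH genes passed, 1544 higher and 1682 lower, of which 1258 differed at least 2-fold, with 5231 at an unadjusted p under 0.05. Higher with dEx1 were GABRR1, at 2.09 ± 0.318 against 0.0164 CPM (SD, n = 3; adjusted p = 0.00875), ITIH3, at 7.14 ± 4.76 against 0.129 CPM (adjusted p = 0.0161), PADI2, at 4.60 ± 3.21 against 0.0904 CPM (adjusted p = 0.0393), the mechanosensitive channel PIEZO2, at 2.53 ± 0.322 against 0.0909 CPM (adjusted p = 0.00246), and TNNT2, cardiac troponin T, at 44.7 ± 20.9 against 2.19 CPM (adjusted p = 0.0175). SBSN, MMP8, GPR84, IL1RN and WNT1 were at 0 in all dEx1 libraries, at least 47.5-fold, 27.01-fold, 19.8-fold, 15.2-fold and 15.1-fold lower than with FL (adjusted p = 0.001000 for SBSN, 0.00293 for MMP8, 0.0116 for GPR84, 0.00481 for IL1RN and 0.00196 for WNT1). ITIH3 was lost without FL replicate 1, TNNT2 without FL replicates 1 or 2, and PADI2 without any FL or dEx1 library (adjusted p up to 0.0652, 0.06997 and 0.106 over their alternatives). The count was 1857 and 1957 without FL replicates 1 and 2 and 2024 and 1981 without dEx1 replicates 1 and 3, and 5138 with the term for replicate 3; 56 of 98 named genes passed under every alternative, 3 lost their call with only the 6 libraries compared and 26 in a fit of all 27.

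In BON-1 the comparison of FL with vector called 1 of 14903 genes, MAML3 itself, with 576 at an unadjusted p under 0.05 and 28 called by DESeq2. No gene other than MAML3 passed, and the values of the gene groups follow. MMP3 stood at 3.52 ± 0.924 against 0.230 ± 0.0554 CPM (SD, n = 3; 3.93, SE 0.67, adjusted p = 0.383), the chemokine CXCL2 at 3.65 ± 1.36 against 0.521 ± 0.259 CPM (2.80, SE 0.47, adjusted p = 0.372) and CXCL8, interleukin 8, at 130.5 ± 62.4 against 43.8 ± 28.7 CPM (1.58, SE 0.54, adjusted p = 0.928). The NF-kB list had a median of 0.38 over 12 members (set test upward 6.12e-06, adjusted p = 0.512 with an estimated correlation), and the proteases 0.08 over 23 members (set test upward 0.00714, adjusted p = 0.512 with an estimated correlation), each with 1 member higher adjusted over the list alone. All 20 cell cycle genes had positive fold changes, with a median of 0.45 (set test upward 4.05e-07, adjusted p = 0.610 with an estimated correlation), and the 20 interferon response genes had a median of -0.41 (set test downward 0.00714, adjusted p = 0.840 with an estimated correlation), with 0 of either list passing adjusted over the list alone in edgeR. Vector replicate 1 stood apart from the other BON-1 libraries, and without it and with a term for replicate 3, the cell cycle median was -0.03 (adjusted p = 0.835) and the interferon median -0.10 (adjusted p = 0.444). Pancreatic endocrine markers had a median of 0.19, or 0.07 with the members at 0 in vector set at their bound, and a mean of 1.08 (set test upward 0.0108, adjusted p = 0.512 with an estimated correlation, 1 member higher adjusted over the list alone). The BON-1 replicates pair, and with the replicate block the adjusted p of the endocrine markers was 0.0730. Without vector replicate 1 and with a term for replicate 3 it was 0.282, with a median of 0.24. HEY1 and HES4 stood at -1.21 (SE 0.36, adjusted p = 0.928) and -0.38 (SE 0.16, adjusted p = 0.928), and the 12 Notch targets had a median of -0.25 (set test 0.126). Without vector replicate 1 and with the term, the Notch median was -0.19 (set test downward 0.00860, adjusted p = 0.196 with an estimated correlation). The 22 lists not called had adjusted p of 0.0652 or more. The count was 3 without vector replicate 1, 2 without FL replicate 1, FL replicate 2 or dEx1 replicate 1, and 4 in a fit of all 27 libraries.

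In BON-1 dEx1 against vector called 2 genes, MAML3 and CLCA1, with 429 at an unadjusted p under 0.05 and 35 called by DESeq2. CLCA1 (hg19 chromosome 1, 86934051 to 86965942), a secreted protein of mucus-producing cells, rose by 4.73 (SE 0.47, adjusted p = 0.0253), from 2.48 to 65.6 ± 24.6 CPM (SD, n = 3). Its fold change stayed between 4.39 and 5.34 under all alternatives, while the adjusted p ranged from 3.84e-26 to 0.265. The adjusted p of CLCA1 in BON-1 dEx1 vs vector was 0.0733 with the replicate block, 0.0814 in a fit of all 27 libraries and 0.265 with only the 6 libraries compared, and the call was lost without any library except vector replicate 1 and dEx1 replicate 3 (up to 0.174). The interferon response had all 20 fold changes negative, with a median of -0.87 (set test downward 9.08e-11, adjusted p = 0.758 with an estimated correlation). IFIT2 stood at 14.2 ± 5.86 against 46.1 ± 24.9 CPM (-1.70, SE 0.59, adjusted p = 0.916) and CXCL10 at -1.43 (SE 0.46, adjusted p = 0.916). The cell cycle genes had a median of 0.54 with 19 of 20 positive (set test upward 3.05e-08, adjusted p = 0.758 with an estimated correlation), and 0 members of either list passed adjusted over the list alone in edgeR. Without vector replicate 1 and with a term for replicate 3, the interferon median was -0.46 (adjusted p = 2.11e-07, 0.522 with an estimated correlation, 0 members called by edgeR), the cell cycle median 0.05 (adjusted p = 0.567) and the endocrine median 0.20 (adjusted p = 0.141). Pancreatic endocrine markers had a median of 0.16, or 0.02 with the members at 0 set at their bound, and a mean of 0.94 (set test upward 0.0320, adjusted p = 0.758 with an estimated correlation, 0.0572 with the replicate block, 1 member higher adjusted over the list alone). HEY1 and HES4 stood at -1.09 and -0.46 (adjusted p = 0.916 for both). The Notch targets had a median of -0.11 (set test 0.418), and -0.13 without vector replicate 1 and with the term (set test downward 0.0216, adjusted p = 0.513 with an estimated correlation). In this comparison the 24 lists not called had adjusted p of 0.207 or more. The count was 1 without vector replicate 2, without any of the 3 FL libraries and without dEx1 replicates 1 or 2.

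In BON-1 dEx1 against FL called 0 genes with edgeR quasi-likelihood, with 156 at an unadjusted p under 0.05 and 8 called by DESeq2. All 12 NF-kB genes were negative, with a median of -0.62 and NFKB2 at 54.6 ± 7.34 against 100.1 ± 18.1 CPM (SD, n = 3; -0.87, SE 0.21, adjusted p = 1.00). MMP10 stood at 19.2 ± 4.98 against 49.9 ± 11.03 CPM (-1.38, SE 0.41, adjusted p = 1.00) and MMP3 at -2.79 (SE 0.62, adjusted p = 1.00). Camera, the set test, gave an adjusted p of 1.83e-11 for the NF-kB genes (adjusted p = 0.295 with an estimated correlation) and 6.90e-05 for the 23 proteases (median -0.16, adjusted p = 0.295 with an estimated correlation), with 1 member lower adjusted over the list alone in each. It gave 3.85e-07 for the interferon response (median -0.43, adjusted p = 0.816 with an estimated correlation), 0.000820 for hypoxia and glycolysis upward (median 0.14, 15 of 16 positive, adjusted p = 0.488 with an estimated correlation) and 0.0380 for 6 Schwann and glial markers (median -0.30, adjusted p = 0.295 with an estimated correlation, 0.101 with the replicate block, 0.0842 without vector replicate 1 and with a term for replicate 3). In these 3 lists 0 members passed adjusted over the list alone in edgeR. The 22 lists not called had adjusted p of 0.0891 or more. The count was 1 without vector replicate 1 or FL replicate 1.

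In BON-1 the FL and dEx1 effects had a correlation of 0.693 across 14902 genes, which are not independent replicates, where simulations of unchanged groups sharing their vector libraries gave a median of 0.508. The covariance was 0.263 against 0.197, a difference of 0.0662. In QGP-1 the correlation was 0.647 across 14521 genes against a simulated 0.509, with a covariance of 0.241 against 0.172, a difference of 0.0695. Among genes of at least 2 CPM the BON-1 correlation was 0.814, with a covariance of 0.0824 against 0.0493. In QGP-1 it was 0.727 there, with a covariance of 0.0480 against 0.0441, a difference of 0.00392. The simulated libraries were independent. They held neither the pairing of the BON-1 replicates nor the 2 QGP-1 clusters, the first of which holds 1 of 3 vector libraries and 2 of 3 for each construct.

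In QGP-1 FL against vector called 4 of 14522 genes, all higher: MMP1, MMP10, KLHL41 and MAML3. MMP10 rose by 4.08 (SE 0.27, adjusted p = 0.00268), from 10.3 to 174 ± 42.7 CPM (SD, n = 3), and MMP1 rose by 5.53 (SE 0.46, adjusted p = 0.00807), from 3.08 ± 0.802 to 142 ± 36.5 CPM. KLHL41, a sarcomeric protein of muscle, rose by 3.06 (SE 0.27, adjusted p = 0.00998), from 0.578 to 4.83 ± 0.390 CPM. MMP10 and MMP1 were the 2 of 21 proteases and inhibitors that passed. The median of the list was 0.09 and the mean 1.00, with 6 higher adjusted over the list alone. The set test gave an adjusted p of 7.85e-10, and adjusted p = 0.0164 with an estimated correlation. CXCL2 was at 1.32 ± 0.798 CPM against 0 with vector (adjusted p = 0.454) and CXCL8 at 2.69 ± 2.92 against 0.198 CPM (adjusted p = 0.702). The 14 ATF4 and ER stress targets had a median of -0.28 and 0 members passing adjusted over the list alone in edgeR (set test downward 0.00538, adjusted p = 0.831 with an estimated correlation). HEY1 stood at -0.60 (SE 0.24, adjusted p = 0.937), and the 14 Notch targets had a median of -0.05 (set test 0.483). With a term for the 2 library clusters the Notch median was -0.23 (set test downward 0.0128, adjusted p = 0.637 with an estimated correlation). The 25 lists not called had adjusted p of 0.0525 or more. At an unadjusted p under 0.05 there were 737 genes, and DESeq2 called 112. The adjusted p of MMP1 and KLHL41 was 0.0537 without vector replicate 2 and 0.0780 without vector replicate 3, the highest for MMP1 over its alternatives (lowest 4.09e-41). For KLHL41 in QGP-1 FL vs vector it was also 0.0532 with only the 6 libraries compared. The count was 1 without vector replicate 3, 31 with a term for the 2 library clusters and 8 with the replicate block. Either cluster alone leaves 1 vector or 1 FL library, which tests no call.

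In QGP-1 dEx1 against vector called 3 genes, all higher: CHTF8, ADIPOR2 and MAML3. CHTF8 (hg19 chromosome 16, 69151913 to 69166491), a subunit of a clamp loader in DNA replication, rose by 2.36 (SE 0.18, adjusted p = 0.00680), from 38.8 ± 5.28 to 199 ± 23.3 CPM (SD, n = 3). ADIPOR2, a receptor for adiponectin, rose by 1.17 (SE 0.12, adjusted p = 0.0355), from 62.2 ± 5.14 to 140 ± 11.1 CPM. The name CHTF8 shares its span with DERPC, which is not analysed here, and overlaps UTP4 and HAS3 on the other strand, so the source of its reads is uncertain. MMP10 stood at 31.0 ± 8.51 against 10.3 CPM (1.59, SE 0.24, adjusted p = 0.259) and MMP1 at 12.6 ± 6.36 against 3.08 ± 0.802 CPM (2.03, SE 0.39, adjusted p = 0.613). ATF4 and ER stress targets had a median of -0.32 (set test downward 0.000675, adjusted p = 0.813 with an estimated correlation). All 20 cell cycle genes were positive with a median of 0.31 (set test upward 0.0104, adjusted p = 0.917 with an estimated correlation), and with a term for the library clusters the median was -0.04 (adjusted p = 0.697). In both lists 0 members passed adjusted over the list alone in edgeR, and the 25 lists not called had adjusted p of 0.0504 or more. At an unadjusted p under 0.05 there were 527 genes, and DESeq2 called 59. The fold change of CHTF8 in QGP-1 dEx1 vs vector stayed between 2.17 and 2.46 under the alternatives. Its call was lost without vector replicates 1 or 3 or dEx1 replicates 1 or 2 and in a fit of all 27 libraries (adjusted p up to 0.388). That of ADIPOR2 stayed between 0.99 and 1.36 and its call was lost without any 1 of the 9 libraries, with the replicate block, with only the 6 libraries compared and in a fit of all 27 libraries (adjusted p up to 0.422). ADIPOR2 also differed within groups of other lines, at 91.8, 96.0 and 198 CPM in the BON-1 vector libraries and 88.0, 44.3 and 92.7 CPM in SK-N-SH dEx1. The count was 0 without vector replicates 1 or 3 or dEx1 replicates 1 or 2, and 1 without FL replicates 2 or 3 or dEx1 replicate 3.

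In QGP-1 dEx1 against FL called 2 genes. CHTF8 was higher by 1.88 (SE 0.17, adjusted p = 0.0381), at 199 ± 23.3 against 54.3 ± 10.0 CPM (SD, n = 3), and MMP10 lower by -2.49 (SE 0.25, adjusted p = 0.0412), at 31.0 ± 8.51 against 174 ± 42.7 CPM. The replicates pair in this comparison, and with the replicate block both had an adjusted p of 0.0945 and the count was 0. The proteases had a median of -0.17, with MMP10 as the only call, 3 of 21 lower adjusted over the list alone and a set test adjusted p of 3.91e-14, and adjusted p = 0.00541 with an estimated correlation. The 10 NF-kB genes had a median of -0.63 (set test downward 7.45e-08, adjusted p = 0.523 with an estimated correlation, 2 lower adjusted over the list alone). The 17 interferon response genes had a median of -0.25, or -0.21 with members at 0 set at their bound (set test downward 4.08e-05, adjusted p = 0.612 with an estimated correlation). The pancreatic endocrine markers had a median of 0.03, a mean of -0.70, or -0.24 at the bound, and a downward set test of 0.00408 (adjusted p = 0.142 with an estimated correlation, 0.0545 with the replicate block, 0.0630 with a term for the library clusters), with 1 member lower adjusted over the list alone, GCG, the glucagon gene, at 0 with dEx1 and 1.21 ± 0.298 CPM with FL. GCG was also at 0 in all 3 vector libraries. The 23 lists not called had adjusted p of 0.271 or more. At an unadjusted p under 0.05 there were 186 genes, and DESeq2 called 19. Both calls were lost when any library except vector replicate 1 was left out, with adjusted p up to 0.156 for CHTF8 in QGP-1 dEx1 vs FL and 0.195 for MMP10 in QGP-1 dEx1 vs FL. Both were also lost with only the 6 libraries compared and in the first cluster alone, and CHTF8 in a fit of all 27 libraries. The count was 7 without vector replicate 1 and 0 without any 1 of the other libraries.

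**Figure D4:**
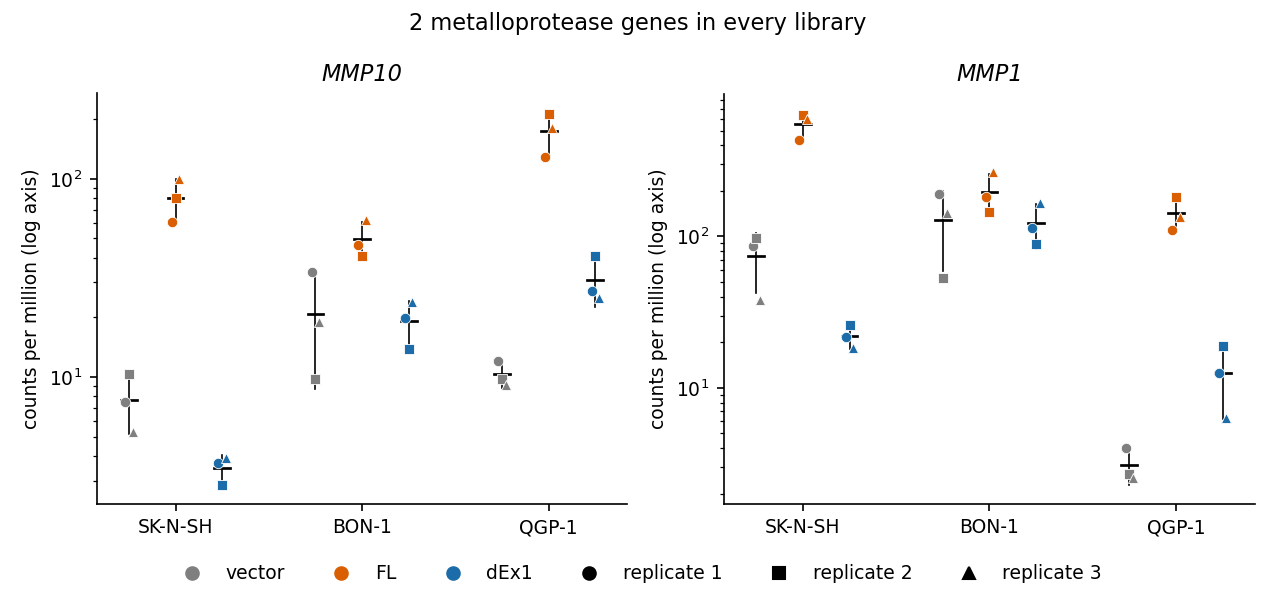
Levels of MMP10 and MMP1 in the 27 libraries, in CPM on a log axis, by line and construct; the point's shape gives the replicate, the black bar is the group mean and the thin bar the SD. MMP10 means with vector and FL are 7.71 and 79.9 CPM in SK-N-SH and 10.3 and 174 CPM in QGP-1.

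Between lines, the effects of each construct were compared across genes. For FL the correlation over genes, which are not independent replicates, was 0.0822 between SK-N-SH and BON-1, 0.0647 between SK-N-SH and QGP-1 and 0.192 between BON-1 and QGP-1. For dEx1 it was 0.0976, 0.0383 and 0.145, and 0.218 between SK-N-SH and BON-1 among genes of at least 2 CPM. Without MAML3, MMP1 and MMP10 were higher with FL in SK-N-SH and QGP-1, 2 of the 3 QGP-1 calls tested in both (Fisher's exact test, p = 0.000132, though these neighbouring genes are not independent). Of 12687 genes tested in all 3 lines, MAML3 was the only 1 called in all of them, for each construct.

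The test of the difference in effect between lines, over 16883 genes, addresses whether a construct acts differently by line. For FL, 48 genes differed between SK-N-SH and BON-1, 31 with a higher effect in SK-N-SH and 17 with a lower one (1583 at an unadjusted p under 0.05). The EREG effect differed (adjusted p = 0.00233): over all 27 libraries scaled together it was at 29.97 CPM with FL and 0.0103 CPM with vector in SK-N-SH, and at 210.9 and 168.2 CPM in BON-1. HAPLN1, a linker of hyaluronan matrix, differed too (adjusted p = 0.0112), with 31.4 and 105.9 CPM with FL and vector in SK-N-SH and 0.598 and 0.0196 CPM in BON-1. Between SK-N-SH and QGP-1 27 genes differed (16 higher, 11 lower, 1459 unadjusted), among them the kisspeptin receptor KISS1R (adjusted p = 0.000447), which was at 0.770 CPM with FL and 0 with vector in SK-N-SH and at 27.1 and 32.0 CPM in QGP-1, and MMP24 at -1.75 (SE 0.29, adjusted p = 0.0112). Between BON-1 and QGP-1 2 genes differed (782 unadjusted): MMP1 by -4.91 (SE 0.63, adjusted p = 0.00214), with 206.5 and 135.3 CPM with FL and vector in BON-1 and 132 and 2.88 CPM in QGP-1, and IFT57 (adjusted p = 0.0178), which was at 0 in QGP-1 vector and 0.162 CPM with FL, and lost its call with the replicate block or with counts divided by 5 (adjusted p up to 0.611 over its alternatives). The MAML3 rise itself was larger in SK-N-SH than in BON-1 for FL, by 3.20 (SE 0.63, adjusted p = 0.0298). The difference from QGP-1, 2.77 (SE 0.62, adjusted p = 0.0771), did not pass, though it did with the replicate block and with DESeq2. The replicate block gave 318, 309 and 12 genes for the 3 FL contrasts and DESeq2 295, 271 and 49.

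For dEx1, 56 genes differed between SK-N-SH and BON-1, 5 with a higher effect in SK-N-SH and 51 with a lower one (1843 unadjusted), and 88 between SK-N-SH and QGP-1, 7 higher and 81 lower (1745 unadjusted). DSP, which encodes the junction protein desmoplakin, differed from both (adjusted p = 8.47e-05 from BON-1, 2.58e-05 from QGP-1), at 0.0143 CPM with dEx1 against 1.87 CPM with vector in SK-N-SH. BTC, the growth factor betacellulin, differed from BON-1 at an adjusted p of 0.000455 and from QGP-1 at 0.000248, at 0 CPM with dEx1 and 0.581 CPM with vector in SK-N-SH. KIAA1324 differed by 1.77 (SE 0.32, adjusted p = 0.0139) and 1.68 (SE 0.32, adjusted p = 0.0150), and FAM117A by 1.15 (SE 0.25, adjusted p = 0.0436) and 1.38 (SE 0.25, adjusted p = 0.00910). The FAM117A difference from BON-1 was lost with no filter and with DESeq2 size factors (adjusted p up to 0.0611 over its alternatives). The MAML3 rise with dEx1 was larger in SK-N-SH by 2.98 (adjusted p = 0.0378) than in BON-1 and by 2.77 (adjusted p = 0.0452) than in QGP-1. Between BON-1 and QGP-1 0 genes differed with edgeR (660 at an unadjusted p under 0.05). The block gave 483, 637 and 6 genes for the 3 dEx1 contrasts and DESeq2 369, 403 and 38.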

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

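Apart from the test of antigen presentation genes given under the other observations, the tests of explanations in this part were chosen only after the result was seen.

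Construct effects that differed between lines are listed here because the difference itself was tested and passed. With FL, 48 genes differed between SK-N-SH and BON-1, 27 between SK-N-SH and QGP-1 and 2 between BON-1 and QGP-1; with dEx1, 56 differed between SK-N-SH and BON-1 and 88 between SK-N-SH and QGP-1. With line labels kept and construct labels redrawn, 3, 7 and 16 of 40 draws gave at least as many genes for FL, and 3, 3 and 40 of 40 for dEx1, where the real count between BON-1 and QGP-1 was 0 with edgeR (660 at an unadjusted p under 0.05, 38 with DESeq2). The highest other draws gave 84, 1485 and 407 genes for FL and 249, 872 and 489 for dEx1. Between SK-N-SH and BON-1 the other draws that reached the real count, 84 and 48 genes for FL and 249 and 98 for dEx1, kept the SK-N-SH libraries in their real groups and so still held that effect. Draws that regrouped SK-N-SH gave at most 7 and 42 there. Between SK-N-SH and QGP-1 the draws with 1485 and 872 genes did regroup SK-N-SH, so chance was not excluded. Between BON-1 and QGP-1 chance was not excluded either.

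Of the genes, EREG (adjusted p = 0.00233), CCDC110 (0.0207) and MAML3 (0.0298) differed between SK-N-SH and BON-1 with FL, KISS1R (0.000447) and IFT57 (0.00191) between SK-N-SH and QGP-1, and MMP1 (0.00214) and IFT57 (0.0178) between BON-1 and QGP-1. With dEx1, KIAA1324 (0.0139), BTC (0.000455) and MAML3 (0.0378) differed between SK-N-SH and BON-1, and KIAA1324 (0.0150), BTC (0.000248) and MAML3 (0.0452) between SK-N-SH and QGP-1. With counts divided by 5 the CCDC110 difference from BON-1 had an adjusted p of 0.216, and both IFT57 differences also lost their call.

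Of the lists, p53 targets differed with FL between SK-N-SH and BON-1 (median difference -0.50, set test adjusted p = 0.00172, 0.127 with an estimated correlation) and between SK-N-SH and QGP-1 (-0.69, 0.000781, 0.0950). Hypoxia and glycolysis genes differed by 0.38 (0.000130, 0.223 with an estimated correlation) and 0.35 (0.000210, 0.253), NF-kB genes between SK-N-SH and BON-1 by 1.04 (0.0345, 0.885), and the interferon response between BON-1 and QGP-1 by -0.60 (0.0112, 0.967). With dEx1 the interferon response differed by -1.01 between SK-N-SH and BON-1 (1.71e-06, 0.603), -1.55 between SK-N-SH and QGP-1 (2.29e-14, 0.182) and -0.80 between BON-1 and QGP-1 (0.00278, 0.863). NF-kB genes differed by -2.19 (1.30e-05, 0.603) and -1.83 (0.00216, 0.473), and proteases between SK-N-SH and QGP-1 by -0.22 (0.000426, 0.149). Further lists passed at the preset correlation. With FL, between SK-N-SH and BON-1, these were cell cycle (-0.45, 0.00904, 0.885), cholesterol synthesis (-0.38, 0.0439, 0.826), ribosomal proteins (0.14, 0.0439, 0.885) and the retinoic acid response (0.28, 0.0439, 0.171). Between BON-1 and QGP-1 they were extracellular matrix (-0.38, 0.0112, 0.134) and cell cycle (0.24, 0.0351, 0.967). With dEx1 ribosomal proteins differed between SK-N-SH and BON-1 (0.18, 0.0165, 0.839) and between SK-N-SH and QGP-1 (0.20, 0.00822, 0.847). In the latter contrast so did Notch targets (-0.29, 0.0287, 0.240), Notch ligands, receptors and coactivators (-0.23, 0.0440, 0.291), mesenchymal neuroblastoma markers (-0.41, 0.0493, 0.182) and Schwann and glial markers (-1.27, 0.0207, 0.149). Without BON-1 vector replicate 1 and with a term for replicate 3, the BON-1 medians were -0.03 in place of 0.45 for cell cycle and -0.10 in place of -0.41 for interferon with FL, and -0.46 in place of -0.87 for interferon with dEx1. The contrasts between lines were not rerun that way, so the differences of these lists from BON-1 are uncertain. No list difference passed with an estimated correlation.

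In SK-N-SH the interferon response was lower with dEx1 than with vector, by a median of -1.63. The replicate 3 libraries stay open as a cause. Every group holds a replicate 3 library, so a term for them hardly moves the fold changes and cannot decide. With that term the median was -1.67. The tables argue against library scaling, which moves every gene alike. The list lay -1.64 from other genes of the same level, with 21 of 21 below them. Less plasmid expression with dEx1 stays open: MAML3 differed by -0.35 between dEx1 and FL (SE 0.39, adjusted p = 0.577), and no transcript of the empty vector is in the table. An effect of the dEx1 protein, which the design names, may also account for it and was not tested apart from transfection. The 10 splits are too few for a share under 0.05; the real split gave 656 genes and the highest other split 1.

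In QGP-1 only 4, 3 and 2 genes were called for FL, dEx1 and their difference. Structure among the libraries stays open: with a term for the 2 clusters the FL count was 31 and the dEx1 count 11, still far below 255 and 656 in SK-N-SH, and the clusters were drawn from the same libraries. The tables argue against lower depth, since the mean total was 1.03 times that of SK-N-SH. A lower MAML3 level stays open, at 0.456 times that of SK-N-SH with FL. It varied within the group (2421, 9001 and 6233 CPM, against 7635 CPM in SK-N-SH FL replicate 3), 3 libraries are too few to relate it to calls, and the lines differ in more than this level.

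In QGP-1 CHTF8 was higher with dEx1, at 199 against 38.8 CPM. The tables argue against reads moved from the overlapping gene UTP4, whose level differed by 4.55 CPM with dEx1 against a CHTF8 gain of 160.6 CPM. Assignment of transcripts to the gene name may account for it, since the within-group spread of CHTF8 in SK-N-SH and BON-1 lay at percentile 98.2 among genes of at least 2 CPM. An effect of dEx1 on CHTF8 itself was not tested apart from this.

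For the other comparisons the 10 splits are again too few for a share under 0.05. At FL against vector and dEx1 against FL in SK-N-SH the real counts were 255 and 3226, and 1 split each, the real one, gave as many (highest other 0 for both with edgeR). At dEx1 against vector in SK-N-SH this was also 1 split. In BON-1 the counts were 1, 2 and 0 for FL, dEx1 and their difference, with 2, 1 and 10 splits giving as many and highest others of 3, 1 and 2. In QGP-1 they were 4, 3 and 2, with 2, 2 and 1 splits giving as many and highest others of 1839, 2960 and 0. The splits with 1839 and 2960 genes are those that follow the 2 clusters, which were drawn from the same libraries.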

How the results depend on the processing

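The alternatives with counts divided by 5, robust spread, MAML3 out of the scaling, terms for libraries that stood apart and subsets of replicates or clusters were chosen after seeing the data; the others were planned, and where no cause is given below, the cause was not tested. Pseudocount alternatives, which apply to normalized values only, were not run.

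In SK-N-SH, DESeq2 called 1168 genes at FL and 1997 at dEx1 against vector. The replicate block gave 778 and 2212, so the main 255 and 656 depend on leaving it out. Only the 6 libraries compared, fewer libraries, gave 28 and 300, and replicates 1 and 2 alone 1020 and 3267. The term for replicate 3 gave 1117, 2714 and, for dEx1 against FL, 5138, with all 255 and all 656 genes called before among the first 2.

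In BON-1 at FL against vector DESeq2 called 28 genes, all 27 libraries in 1 fit 4, MAML3 out of the scaling 0 and vector replicate 1 out with a replicate 3 term 19. At dEx1 against vector these were 35 with DESeq2, 1 with the 6 libraries, 1 with MAML3 out of the scaling and 7 with the term. MAML3 itself was not tested where it was left out of the scaling, which lowers those counts by 1, and CLCA1 in BON-1 dEx1 vs vector stayed called there (4.74, adjusted p = 0.0470). At dEx1 against FL they were 8 with DESeq2, 1 with all 27 libraries and 3 with the term.

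In QGP-1 at FL against vector DESeq2 called 112, the block 8, all 27 libraries 19, the 6 libraries 2 and the cluster term 31. At dEx1 against vector DESeq2 called 59, the 6 libraries 1 and the cluster term 11. At dEx1 against FL no filter gave 5, DESeq2 size factors 4, DESeq2 19, the block 0, the 6 libraries 0, counts divided by 5 5 and the cluster term 7. Fits of a single cluster gave 78 and 8 at FL against vector, 39 and 9 at dEx1 against vector and, in the second cluster, 14 at dEx1 against FL. Apart from dEx1 against FL in the first, they leave an arm of 1 library, with the spread taken from the other groups, and test no call.

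MAML3 in QGP-1 kept its direction in every alternative run, while its adjusted p rose above the threshold with the block for dEx1 (5.84, 0.0520), the 6 libraries (6.33, 0.109 for FL; 5.98, 0.0652 for dEx1), the first cluster (6.19, 0.0958; 5.78, 0.122) and the second (6.47, 0.107; 6.21, 0.104), the last 3 with fewer libraries and the clusters with an arm of 1.

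For the contrasts between lines the block gave 318, 309 and 12 genes for FL and 483, 637 and 6 for dEx1, and DESeq2 295, 271 and 49, and 369, 403 and 38. A minimum of 2 CPM gave 94 for dEx1 in SK-N-SH against BON-1, and counts divided by 5 gave 1 for FL in BON-1 against QGP-1.

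Lists called numbered 4, 8 and 8 in SK-N-SH, 5, 3 and 5 in BON-1 and 2, 2 and 4 in QGP-1. With an estimated correlation 0 lists passed camera in 7 of the 9 comparisons and 1 in QGP-1 at FL against vector and at dEx1 against FL. Fry called 2, 1 and 0 in BON-1 and 1, 0 and 1 in QGP-1. The block gave 5 at FL against vector in QGP-1, and the terms for libraries that stood apart gave 5 at dEx1 against vector in BON-1 and 6 at FL against vector in QGP-1. At a minimum of 2 CPM the correlation of the construct effects was -0.257 in SK-N-SH and 0.814 in BON-1, and that of the dEx1 effects of SK-N-SH and BON-1 0.218.

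Leaving out 1 library gave 21 to 364 genes at FL against vector, 80 to 2558 at dEx1 against vector and 1857 to 4024 at dEx1 against FL in SK-N-SH, 1 to 3, 1 to 2 and 0 to 1 in BON-1, and 1 to 6, 0 to 3 and 0 to 7 in QGP-1. MAML3 against vector ranged from 8.85 to 9.39 for FL and 8.34 to 9.04 for dEx1 in SK-N-SH, 5.65 to 6.11 and 5.68 to 5.85 in BON-1, and 5.88 to 6.68 and 5.69 to 6.27 in QGP-1.

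Of 4737 values of named genes under alternatives, 3961 kept their direction and side of the threshold, 774 lost the call, 2 gained it and 0 reversed. Of genes changed 1.5-fold in simulated data, edgeR called 14% in SK-N-SH, 0% in BON-1 and 6% in QGP-1, and DESeq2 46%, 18% and 24%. Depth was not varied in the simulations. With counts divided by 5 the calls of named genes in the 3 SK-N-SH comparisons held in 47 of 47, 58 of 58 and 98 of 98 cases. Between lines the same division ended 6 of 11 named values for FL in SK-N-SH against BON-1, 4 of 11 against QGP-1 and 1 of 3 in BON-1 against QGP-1, and for dEx1 4 of 10 and 2 of 11 in SK-N-SH against BON-1 and QGP-1.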

Other observations

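The test of antigen presentation genes was written before their values were seen; the lists themselves and all the other tests of this part were chosen after the data had been seen.

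In SK-N-SH with dEx1, genes of antigen presentation, which interferons induce, were lower, with 10 of 11 passing the test and all 11 negative (median -1.37, set test adjusted p = 0.0334 with an estimated correlation). HLA-C fell by 2.09 (SE 0.31, adjusted p = 0.0126) and B2M fell by 1.37 (SE 0.22, adjusted p = 0.0145), with n = 3 per group.

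Of 10 nucleic acid sensors, 7 passed downward with dEx1 in SK-N-SH and 8 were negative (median -1.33, adjusted p = 0.0334). IFIH1 and DDX58 are also in the interferon list. TLR3, which binds double-stranded RNA, fell by 1.83 (SE 0.24, adjusted p = 0.00883), and AIM2, a DNA sensor, fell by 3.67 (SE 0.57, adjusted p = 0.0141).

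Metalloprotease genes of the cluster on hg19 chromosome 11, from MMP7 (102391239) to MMP13 (102826461), were all higher with FL in SK-N-SH, and 5 of 7 passed (median 3.15, adjusted p = 0.000814). MMP12 rose by 3.99 (SE 0.23, adjusted p = 0.000525), from 2.03 to 32.3 CPM, and is named outside the rule, chosen after its values were seen. The 12 metalloproteases at other loci had a median of -0.31 (adjusted p = 0.320 with an estimated correlation). With the members left out that the rule had named as calls for FL, the medians of the cluster and the other loci differed by 2.66 in SK-N-SH (3 genes, exact permutation p = 0.0132, adjusted 0.0198), by 0.906 in BON-1 (6 genes, exact p = 0.0267) and by 3.84 in QGP-1 (4 genes, mostly near the floor, exact p = 0.00699, adjusted 0.0198). The remaining members had been seen too, among them MMP12, so this test was not made on unseen genes. Genes of a cluster are not independent, and whether the cluster responds as 1 stays open in all 3 lines.

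All 7 interleukin 1 family genes were higher with FL in SK-N-SH, and 3 passed (median 1.29, adjusted p = 0.0505). All 7 were lower with dEx1 than with FL, and 6 passed (median -8.25, or -3.26 with genes at 0 set at their bound, adjusted p = 0.0541). Of 8 EGF family ligands EREG was the only call with FL (adjusted p = 0.121 for the list). Against FL, 7 were lower with dEx1, and 3 passed (median -0.92, adjusted p = 0.0407).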
